A study of Homo sapiens with 12 samples.

How the data were processed

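The 12 libraries were ChIP and matched input DNA of H2228 and H3122 cells with mutant p53, per the labels crosslinked with 1% formaldehyde, amplified for 14 PCR cycles and sequenced in paired reads of 100 bp on a NovaSeq 6000. The submitters' processing notes name hg38, Trim Galore 0.4.4, Bowtie2 2.3.4, Picard, MACS2 and bedtools, with no role or order. Per the file headers, each of the 4 peak tables deposited by the authors gives every peak's position and summit, with 1 line per peak and gene annotation, and the labels give 30000000 to 40000000 reads per sample. Whether replicates were pooled before peak calling is not given in the sources used here, and the antibody is known only from the V5 in the peak names.

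Per the file headers, the pileup is the signal (coverage) at the summit as the authors deposited it. The fold enrichment is the authors' deposited ratio of pileup to local background, and dividing the pileup plus 1 by it gives a sharply repeated lowest background of 1.94, 2.02, 2.23 and 2.21 after subtracting 1, in the order H2228 R175, H2228 R273, H3122 R175 and H3122 R273. The -log10 p-value and -log10 q-value columns are the authors' deposited significance of each peak against input. The smallest -log10 p was just above 3 in each table, so 1250, 772, 503 and 578 peaks had a q above 0.05. Every listed peak has a gene feature and the peak numbers have gaps of 3819, 1668, 10190 and 12459, so peaks outside gene features were not analysed here. No control without the tagged protein was used here.

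Genes came from a RefSeq table of GRCh38.p14, whose chromosomes 1 to 22, X and Y share coordinates with hg38. Of 22303 gene IDs in the peak tables, 22258 matched it. It gives no strand, so strand was taken from the peak tables for 15593 of 20033 protein-coding genes, and the other 4440 counted as not occupied, of which 223 had a peak within 1 kb of an end. A promoter was 1 kb to each side of the 5 prime end of the gene, which lay within 50 bp of a transcript start of the tables for 81.5% of genes. Where several peaks overlapped a promoter the highest fold enrichment was taken, and 1 peak can serve neighbouring genes. Fold enrichments were not compared between tables, except that a mean over the tables with a peak chose some of the genes named, which can favour genes with a peak in H3122 alone since the median promoter fold enrichment was 4.60, 4.39, 6.17 and 5.52 in the same order.

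Peaks overlapped when they shared at least 1 bp. Overlap and promoter shares were set against 100 circular shifts along each chromosome and, added after the data were seen, 100 shifts within genes and 5 kb to each side, since every listed peak has a gene feature. Neither kind of shift keeps peaks at promoters, so an overlap above it could come from promoter peaks in both tables. List occupancy was tested by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. Differences between mutants were given as the percentile among 10000 random lists of genes with a promoter peak in either table, with no p-value, since there is 1 table per combination. Lists matched on the -log10 q of the R175 peak, lists matched on chromosome, percentiles of list fold enrichment, the test of general promoter occupancy and that of recurrence between lines were added after the data were seen. The lists and the rule for named genes were fixed before the data were examined. Named genes were the 3 members of each list with the highest promoter fold enrichment averaged over the tables that have one, members that differed between mutants in both lines, the 5 highest promoters of each table and of each side of each pair, the 5 with the highest such mean among promoters with a peak in all 4 tables, the 3 highest distal peaks of each table, and CDKN1A, MDM2, EML4 and ALK. Some genes that this rule takes are not reported here. Alternatives were stricter peaks (a -log10 q or a fold enrichment of at least 5), the same number of peaks per table, the 5000 highest peaks, a reciprocal overlap of 0.5, summits within 200 bp, promoters of 500 bp and 3 kb, the tables' own promoter annotation, and a background of genes with a promoter peak in at least 1 table.

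Statistics were checked on simulated data. A planted overlap of 40.1% between 14481 H2228 R273 peaks and a set of the size of H2228 R175 was recovered as 40.5%. Over 20033 genes at the occupancy of H2228 R175, the list test called 5.10% of lists of 36 genes without enrichment and 89% of those with an odds ratio of 3. Over 20033 simulated genes whose loss depended on q alone, 7% of lists of weak peaks lay above the middle 95% of random lists after matching and 99% before. The nominal share above that range is 2.5%, so matching did not remove all of the excess. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Tests of DNA motifs and of promoters matched on CpG content need a genome and were not run, and tests on values per library were not run because the tables hold 1 set of peaks per line and mutant.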

Results

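Mutant p53 carrying the R175H or the R273H substitution was mapped by chromatin immunoprecipitation and sequencing in H2228 and H3122, human lung adenocarcinoma lines with an ALK gene fusion. The peak names carry the tag V5, an epitope used to pull down a tagged protein. The series title ties mutant p53 to DNA replication and repair. The 12 libraries comprised 2 ChIP replicates for each of the 4 combinations of line and mutant, and 1 input for each. The labels call the source a patient-derived xenograft while naming established cell lines. The values came as 1 peak table per combination, so no value per replicate was used and differences between tables have no replicate error. The labels give 30000000 to 40000000 reads per sample, and the read totals of single libraries were not analysed here. Positions are those of hg38. Fold enrichments and q values are the authors' own values for each peak, and their scale can differ between tables. List members were named by their mean fold enrichment over the tables with a promoter peak, which chooses names and ranks no promoter.

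Promoters held a larger share of the peaks in H2228 than in H3122, by less when equal numbers of peaks were compared. In H2228, 23549 peaks were listed for R175 and 14497 for R273, and in H3122 50233 and 59004. The share of peaks within 1 kb of the 5 prime end of a protein-coding gene was 45.4% for H2228 R175 and 54.1% for H2228 R273. In H3122 promoters held 27.2% for R175 and 24.2% for R273. With the same number of peaks per table the shares were 52.3 and 54.1% in H2228 and 45.8 and 42.6% in H3122, and with the 5000 highest peaks, in the same order, 61.7, 62.1, 54.5 and 50.3%. Exact 95% binomial intervals of the shares over all listed peaks, which cover counting error only, ran from 44.7 to 46%, 53.3 to 55%, 26.8 to 27.6% and 23.9 to 24.6% in that order. Peaks placed at random within genes and 5 kb to each side gave 2.22% ± 0.116 (SD over 100 placements) for H2228 R175 and 2.28% ± 0.0986 for H3122 R273. In the tables' own annotation 28.3, 19.9, 44.3 and 47.6% of peaks lay in introns without a promoter or exon feature. The one-sided permutation p of the promoter share was 0.00990 in each table, the smallest that 100 placements can give.

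The promoters with the highest fold enrichment differed from table to table. KAT6A, a histone acetyltransferase gene, led H2228 R175 with a fold enrichment of 19.7 (chromosome 8, 42051457 to 42052349), and KMT2A, a histone methyltransferase gene, at 19.6, NDUFS7 at 18.9 and NSFL1C at 17.3 were also among its highest. In H2228 R273 the highest were ZNF341 at 22 (chromosome 20, 33731921 to 33732475), SMARCD2, a chromatin remodelling subunit, at 20.9, CLTC, which encodes the clathrin heavy chain, at 17, and HIRA and MRPL40, which share 1 peak, at 16.2. H3122 R175 was led by SMG1, a kinase of nonsense-mediated decay, at 20.6 (chromosome 16, 18925353 to 18927207), with DNAJB2 and PRC1 at 18.9, and BHLHE40 and NAB2 at 18.1. In H3122 R273 the shared peak of FKBP2 and LOC114841035 reached 21.2 (chromosome 11, 64239447 to 64242395), TMEM184A 19.2, ARRDC1 17.1 and HAPSTR1 16. A promoter peak was found in all 4 tables for 6734 of 20033 protein-coding genes, among them SMARCD2, CLTC, ZNF341, NSFL1C and PTMA, the prothymosin alpha gene, which had the highest means over the tables. At PTMA the fold enrichment was 13.3 in H2228 R175, 9.39 in H2228 R273, 14.8 in H3122 R175 and 12.7 in H3122 R273.

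Away from the 5 prime ends of protein-coding genes, the highest peak of H3122 R175 lay in an intron on chromosome 18, 3305160 to 3305713, with a fold enrichment of 23.4. A peak over the same place was listed in each table, with 15.6 in H2228 R273. The next in H3122 R175 were an intronic peak on chromosome 2, 177169832 to 177170730 at 21.8 and 1 in PRAG1 (chromosome 8, 8362631 to 8363362) at 21.2. H2228 R175 had its highest such peaks at ADPRHL1 (chromosome 13, 113448873 to 113449717) with 17.3, ZBTB45 (chromosome 19, 58518868 to 58520454) with 16.5, and the GEMIN7, MARK4 and ZNF296 region (chromosome 19, 45078995 to 45079450) with 15.7. These 3 carry a promoter feature in the tables' own annotation. In H2228 R273 ZBTB45 had 13.3 and an intron at GAS6 and GAS6-AS1 (chromosome 13, 113837218 to 113837777) 12.6. H3122 R273 was led by an intron of LRP5L (chromosome 22, 25400491 to 25401641) at 19.3, followed by the HM13-AS1 and LOC107985416 region (chromosome 20, 31572500 to 31574530) at 17.7 and LINC01503 (chromosome 9, 129333631 to 129335028) at 17.3. The H2228 R273 peak at ZBTB45 and the last 2 of H3122 R273 also carry a promoter feature there.

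Promoters of DNA replication and repair genes were occupied more often than those of other protein-coding genes in H2228 R175 and both H3122 tables among all listed peaks, as were those of most other lists. In H2228 R273 this held for excision and mismatch repair among these lists, and in H2228 several of these calls were lost with stricter peaks. Against a background of the 12927 genes with a promoter peak in at least 1 table, no replication or repair list passed the test in any table. Of that background 11942 genes were occupied in H3122 R175 and 12035 in H3122 R273. Lists of this size therefore had little room to pass in H3122, where this test cannot decide. For DNA replication, 37 of 51 promoters had a peak in H2228 R175 (Fisher's exact test, adjusted p = 0.00188), 23 of 51 in H2228 R273 (adjusted p = 0.334), 48 of 51 in H3122 R175 (adjusted p = 2.28e-07) and 49 of 51 in H3122 R273 (adjusted p = 3.36e-08). Among them, POLD1, which encodes the catalytic subunit of DNA polymerase delta, had fold enrichments of 5.40, 7.79, 9.85 and 9.95 in that order, ORC4 3.97, 4.39, 8.49 and 12.8, and MCM7, a subunit of the replicative helicase, 8.79, 4.98, 8.77 and 6.85. For homologous recombination and Fanconi anaemia genes, the counts were 30 of 36 (exact test, adjusted p = 8.84e-05), 14 of 36 (adjusted p = 1), 34 of 36 (adjusted p = 1.37e-05) and 34 of 36 (adjusted p = 1.45e-05). Excision and mismatch repair genes had 22 of 32 (exact test, adjusted p = 0.0423), 23 of 32 (adjusted p = 0.000324), 32 of 32 (adjusted p = 7.09e-07) and 29 of 32 (adjusted p = 0.000398). Among them ERCC1 had 8.30, 6.02, 12.2 and 6.84, PARP2 4.42, 5.64, 14.1 and 8.94, and RAD23B 8.16, 5.47, 9.40 and 9.66. Tests were Fisher's exact, two-sided, adjusted by the Benjamini-Hochberg method over 84 tests of 21 lists in 4 tables. They run across genes of 1 table, not across replicates. In H2228 R175 the exact tests gave an adjusted p of 0.370 at a -log10 q of at least 5, 0.542 at a fold enrichment of at least 5 and 0.753 with the 5000 highest peaks for DNA replication, 0.0217, 0.0822 and 0.0516 for recombination, and 0.199, 0.0691 and 0.360 for excision and mismatch repair, which also had 0.0899 for promoters of 3 kb and, in H2228 R273, 0.256, 0.135 and 0.101. In H3122 these lists passed at that q and that fold, and with the 5000 highest peaks the exact test was passed only by excision and mismatch repair in H3122 R273 (adjusted p = 0.0458).

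Shares of occupied promoters are given in the order H2228 R175, H2228 R273, H3122 R175 and H3122 R273. End joining genes such as LIG4, PAXX and RIF1 had 80%, 53.3%, 93.3% and 100%, and checkpoint genes such as ATR, ATM and WEE1 had 84.2%, 52.6%, 100% and 100%. Cell cycle genes such as E2F3, KIF20A and AURKA had 68.8%, 53.1%, 96.9% and 93.8%, and nucleotide synthesis genes such as NME1, GMPS and PPAT had 80%, 56%, 96% and 92%. Mevalonate pathway genes such as SREBF2 and LSS had 81.2%, 43.8%, 87.5% and 87.5%, and proteasome subunits such as PSMC5, PSMD8 and PSMD14 had 77.4%, 51.6%, 96.8% and 96.8%. Chromatin regulators such as KMT2A, KAT6A and SETD1B reached 91.3%, 87%, 95.7% and 91.3%. ALK and receptor tyrosine kinase signalling genes such as DUSP6 and PHLDA1 reached 94.1%, 82.4%, 97.1% and 97.1%, and antioxidant response genes such as NFE2L2, ME1 and KEAP1 had 73.7%, 63.2%, 84.2% and 84.2%. Lung and epithelial identity genes such as CLDN4 and the KRT8 and KRT18 pair, which share 1 peak, had 68.2%, 68.2%, 86.4% and 81.8%. Of the genes named here, ATM, PSMC5 and SETD1B had no promoter peak in H2228, and E2F3, KIF20A, GMPS, PPAT and ME1 had none in H2228 R273. Of the 21 lists, 15, 8, 16 and 15 were occupied more often than other genes and 4, 4, 3 and 4 less often. End joining, checkpoint, cell cycle, nucleotide synthesis, mevalonate pathway and proteasome lists passed in H2228 R175 and both H3122 tables and not in H2228 R273. Lung and epithelial identity passed in H2228 R273 and H3122 R175 alone, and the chromatin, receptor tyrosine kinase and antioxidant lists passed in each table. With stricter peaks by q or fold, the checkpoint, chromatin and receptor tyrosine kinase lists kept these calls. Cell cycle, nucleotide synthesis, mevalonate pathway, proteasome and antioxidant lists lost theirs in H2228 R175 at both settings, as did the antioxidant list in H2228 R273 and the mevalonate list in H3122 R273. At that fold alone end joining lost its call in H2228 R175 and H3122 R175, lung and epithelial identity in H2228 R273, and the cell cycle and antioxidant lists in H3122 R273, and at that q alone nucleotide synthesis in H3122 R273. End joining passed in H2228 R273 at both settings, and lung and epithelial identity in H2228 R175 and H3122 R273 at that q. With the same number of peaks per table the cell cycle and mevalonate lists lost their calls in H2228 R175 and H3122 R273, the antioxidant list in H3122 R273, and lung and epithelial identity in H3122 R175.

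Comparator groups marked the range. Highly transcribed genes such as ALDOA, PKM and HNRNPA2B1 were occupied at 93.3%, 86.7%, 96.7% and 96.7%, and ribosomal protein genes such as RPL18, RPS16 and RPS19 in 71 of 81, 59 of 81, 76 of 81 and 79 of 81 cases. Genes of blood and immune cells such as CD14, CSF1R and CD79A had 14.3%, 10.7%, 21.4% and 17.9%, and neuronal genes such as SLC17A7, SNAP25 and MBP had 15.4%, 3.85%, 19.2% and 19.2%. Of 392 olfactory receptor promoters, 2 had a peak in each table, at OR1F1 and OR10H1. Replication-dependent histone genes such as H4C8 and the H2AC20 and H2BC21 pair had 32.9%, 20%, 50% and 45.7%, and mesenchymal markers such as COL1A1, SNAI1 and TGFBI had 31.2%, 31.2%, 62.5% and 56.2%. Of these genes, CD79A and H4C8 had no promoter peak in H2228, TGFBI had none in H2228 R175, and ALDOA, SLC17A7 and MBP had none in H2228 R273. Mesenchymal markers passed the test in no table among all listed peaks, and the smallest adjusted p among their 4 exact tests was 0.233. Highly transcribed and ribosomal protein lists lay above other genes in each table, and immune, neuronal and olfactory receptor lists below. The histone list lay below in each table but H3122 R175 (exact test, adjusted p = 0.128). With stricter peaks by q or fold, the neuronal and histone lists lost their calls in H2228, as did the immune list by fold, and with stricter or equal numbers of peaks the histone list lay below in H3122 R175. Mesenchymal markers lay below other genes in H3122 R273 with the same number of peaks per table (exact test, adjusted p = 0.0244). Against the background of genes with a promoter peak in at least 1 table, 1 of the 84 exact tests passed, that of highly transcribed genes in H2228 R273 (adjusted p = 0.0389). In H3122 most of that background was occupied, so lists there had little room to lie above it.

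**Figure D1:**
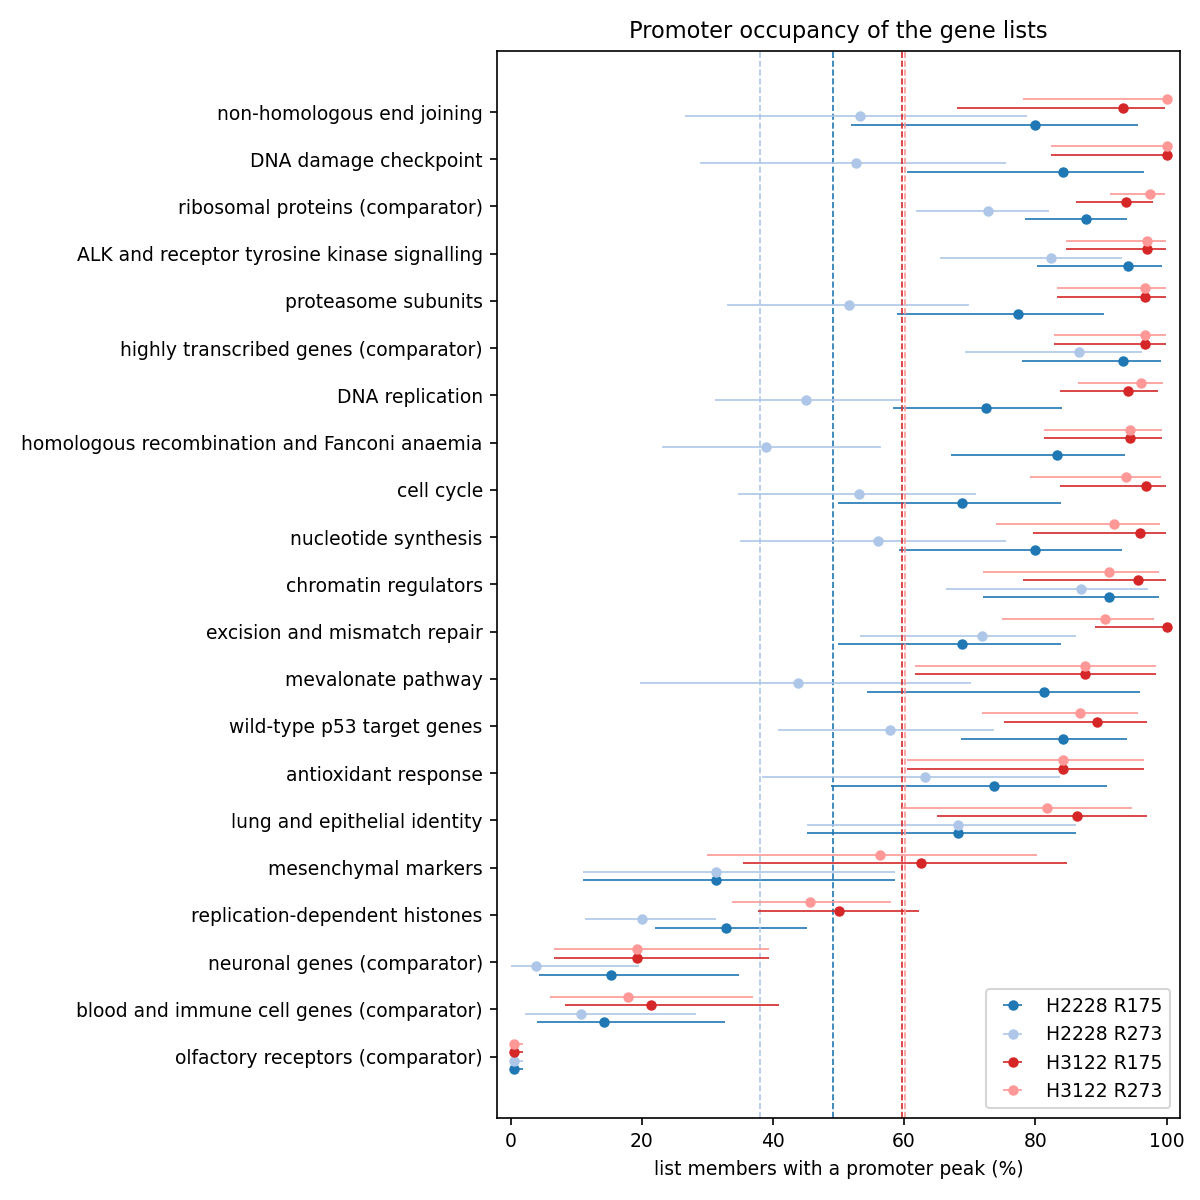
Share of list members with a promoter peak (percent, horizontal axis) for each gene list (vertical axis) in the 4 peak tables, with exact 95% binomial intervals that cover counting error only, and dashed lines at the share over all protein-coding genes. Repair and replication lists lie near the highly transcribed and ribosomal protein comparators in H3122, and olfactory receptors lie at 0.510% in each table.

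Wild-type p53 target genes had promoter peaks in 32 of 38 cases in H2228 R175 (Fisher's exact test, adjusted p = 3.43e-05), 22 of 38 in H2228 R273 (adjusted p = 0.0255), 34 of 38 in H3122 R175 (adjusted p = 0.000193) and 33 of 38 in H3122 R273 (adjusted p = 0.000814). At the peaks of SESN1, a stress response gene, the fold enrichments were 6.59, 5.44, 14.2 and 12.4 in that order, at SUSD6 7.04, 5.94, 10.5 and 13.6, and at GADD45A 3.40, 5.02, 12.2 and 11.2. GADD45A had no promoter peak in H2228 R175 with stricter or equal numbers of peaks, within 500 bp or in the tables' own annotation, and none in H2228 R273 at a -log10 q of at least 5. In H2228 R273 the exact test of the list gave an adjusted p of 0.144 at that q and 0.0565 with the 5000 highest peaks. The list's shares of 84.2, 57.9, 89.5 and 86.8% lay below those of highly transcribed genes (93.3, 86.7, 96.7 and 96.7%). They also lay below those of ribosomal protein genes in each table. Against genes with a promoter peak in at least 1 table the list passed in none, though in H3122 it had little room to pass. At CDKN1A, which encodes the cell cycle inhibitor p21, a peak over the 5 prime end of the gene was listed in H2228 R273 (chromosome 6, 36676276 to 36676593) with a fold enrichment of 5.64, in H3122 R175 (36676218 to 36676738) with 11.9 and in H3122 R273 (36676224 to 36676718) with 2.90. The H3122 R273 peak had a -log10 q of 2.16 and lay below both stricter settings. No peak was listed over the 5 prime end in H2228 R175, whose first peak over the gene began at 36678634. That peak carried promoter, exon, intron and 5 prime UTR features of annotated transcripts, and each other table had an overlapping peak with these features. Fold enrichments at this second place were 4.26 in H2228 R175, 4.71 in H2228 R273, 10.7 in H3122 R175 and 7.76 in H3122 R273. Further into the gene, H3122 R273 had a peak with 9.66 (36682457 to 36683558), and overlapping peaks had 5.11 in H2228 R175 and 8.21 in H3122 R175. MDM2, which encodes the main negative regulator of p53, had promoter peaks in all 4 tables, with 5.04, 4.02, 11.6 and 9.83, of which that in H2228 R273 was lost with stricter peaks.

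**Figure D2:**
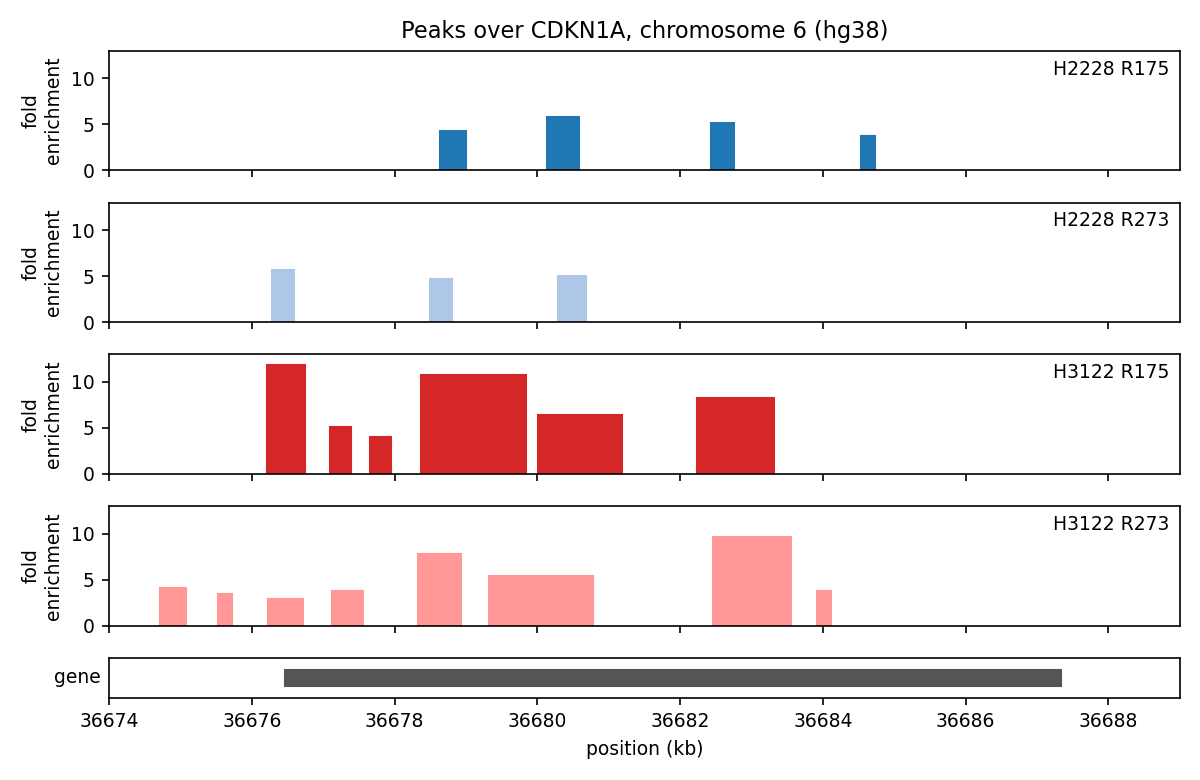
Peaks over CDKN1A on chromosome 6 (position in kb, horizontal axis), drawn as blocks from start to end with the fold enrichment of each peak as height, in 1 panel per peak table, above the extent of the gene. The peak over the 5 prime end reached 11.9 in H3122 R175, and none was listed there in H2228 R175.

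EML4, a gene that fuses with ALK in lung adenocarcinoma, had a promoter peak in each table, with 5.13 in H2228 R175, 5.11 in H2228 R273, 6.26 in H3122 R175 and 8.48 in H3122 R273. Over ALK, 4 peaks were listed in H2228 R175, 0 in H2228 R273, 15 in H3122 R175 and 18 in H3122 R273. The 4 in H2228 R175 were weak, with fold enrichments from 3.06 to 3.89 and -log10 q from 1.17 to 3.36, below both stricter settings. The R175 table of H2228 also held 1.62 times as many peaks as the R273 table, and the H3122 tables held more still. These counts therefore show no difference between mutants or lines at ALK.

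In H2228 most R273 peaks overlapped an R175 peak by at least 1 bp. Among all listed peaks, of which R175 had 1.62 times as many, fewer promoters had a peak for R273 alone than for R175 alone. Of the R273 peaks, 75.1% overlapped an R175 peak, against 1.30% ± 0.114 (SD) for placement within genes, and 45.6% of R175 peaks overlapped an R273 peak (permutation p = 0.00990 in each case, the smallest possible). Placed peaks mostly lay away from promoters, so 2 sets rich in promoter peaks would exceed this level. Placement therefore cannot tell sites common to the mutants from a general place at promoters. With a reciprocal overlap of at least 0.5 the overlaps were 45.3 and 27.9%, and with the same number of peaks per table they were 61.5 and 59.1%. Promoter peaks were listed for 6912 genes with both mutants, 2941 with R175 only and 703 with R273 only. R175-only promoters with the highest fold enrichment were POR, the cytochrome P450 reductase gene, at 9.52, RHOT2 at 8.80, LOC124900372 (chromosome 16) and SUGT1 (chromosome 13) at 8.50 each, and SMG8 at 8.47. On the R273 side they were the shared peak of PRH1, PRH1-TAS2R14 and SMIM10L1 at 7.83, MYLIP at 7.52 and TANC1 at 7.40, of which SMIM10L1 had no promoter peak for either mutant in the tables' own annotation.

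Of the 18 lists compared in H2228, homologous recombination and Fanconi anaemia genes had the widest gap between the mutants, with 83.3% of promoters occupied for R175 and 38.9% for R273. Of 30 members with a promoter peak for either mutant, 14 had one for both, 16 for R175 only and 0 for R273 only, a difference that lay at percentile 99.94 of 10000 random lists. RAD54L, a recombination motor protein gene, had 8.16 and FANCG, a Fanconi core complex gene, 5.63 in R175 with no peak in R273, and FANCE had none in either. BLM, FANCA, FANCD2, FANCI, BRIP1 and RAD50, named after their values were seen, were also among the R175-only promoters, while BRCA2 and PALB2, also named after their values were seen, had a peak with both mutants. Excision and mismatch repair genes lay at the other end, with 3 promoters for R175 only and 4 for R273 only among 26 (percentile 0.965), and DNA replication genes had 16 and 2 among 39 (percentile 95.2). With stricter peaks the recombination list no longer lay outside the middle 95% of random lists, at percentile 81.4 for a -log10 q of at least 5 and 68.2 for a fold enrichment of at least 5, nor did excision and mismatch repair, at 56.4 and 54.6, or at 8.33 with the same number of peaks per table. These were the 2 of 18 lists outside that range in H2228 among all listed peaks, and with 1 table per mutant they have no replicate check. No correction was made for the number of lists compared, and 5% of simulated random lists lay outside that range. Other lists lay outside it under other settings. DNA replication lay at percentile 98.1 at that q and 98.3 for promoters of 500 bp, and checkpoint genes at 99 at that fold. Chromatin regulators lay at 0.0550 and 0.790, with 1 and 2 promoters for R175 only and 5 and 5 for R273 only, where all listed peaks gave 1 and 0 (percentile 8.62).

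In H3122 most promoters with a peak had one for both mutants. Promoter peaks were listed for 11264 genes with both, 678 with R175 only and 771 with R273 only, and 70.1% of R175 peaks overlapped an R273 peak, against 3.61% ± 0.172 (SD) placed within genes (permutation p = 0.00990). The reverse share was 60.8%. Here too placed peaks mostly lay away from promoters, which limits this comparison as in H2228. Of 35 recombination and Fanconi anaemia promoters with a peak, 33 had one with both mutants (percentile 55.3), and of 49 replication promoters 48 did (percentile 39.4). All 19 checkpoint promoters had a peak with both mutants, and excision and mismatch repair had 3 for R175 only and 0 for R273 only (percentile 95.1). R175-only promoters with the highest values were IGFLR1 at 9.40, SNN at 7.93, FNBP1 and GPR107, which share 1 peak, at 7.93, and FAM72A at 7.67. R273-only promoters were RAD54B, a recombination gene outside the list, at 8.41, LOC124902766 at 8.10, SNU13 at 7.77, PID1 at 7.48 and PARVA at 7.05. With promoters of 3 kb, IGFLR1, FAM72A, SNU13, PID1 and PARVA had a peak with both mutants, as did IGFLR1, FNBP1, FAM72A, SNU13 and PARVA in the tables' own annotation. Within 500 bp IGFLR1, FAM72A and SNU13 had a peak with neither, and among the 5000 highest peaks SNN, FNBP1, GPR107, LOC124902766 and PID1 had none. No list lay outside the middle 95% of random lists in H3122 among all listed peaks, where most list promoters were occupied with both mutants. Under other settings some did, among them DNA replication at percentile 0.805 for a fold enrichment of at least 5 and excision and mismatch repair at 99.5 for promoters of 500 bp.

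Few promoters had a peak for 1 mutant only in both lines. For R175 these were 139 genes, against 154 ± 10.6 (SD) for independent sets of 12927 genes, and for R273 41 against 41.9 ± 6.11. No conclusion is drawn from this comparison, because independent sets failed for promoters with opposite mutants in the lines. There were 148 promoters R175 only in H2228 and R273 only in H3122, below the range of 154 to 198 for independent sets. Among list members, the R175-only promoters in both lines were TOP2A, which encodes topoisomerase II alpha, NRAS, HBA1, and the H2AC15 and H2BC15 pair, which share 1 peak. TOP2A had 3.40 in H2228 and 4.26 in H3122, and NRAS 5.10 and 5.03. With promoters of 3 kb TOP2A and HBA1 had a peak with both mutants in H3122. With stricter or equal numbers of peaks TOP2A, HBA1, H2AC15 and H2BC15 had no R175 peak in either line, and with equal numbers NRAS had none in H3122.

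Between the lines, most H2228 peaks overlapped an H3122 peak of the same mutant by at least 1 bp, and a smaller share of the H3122 peaks overlapped an H2228 peak. Of H2228 R175 peaks, 82.2% overlapped an H3122 R175 peak, against 2.94% ± 0.163 (SD) placed within genes, and of H2228 R273 peaks 90% overlapped an H3122 R273 peak, against 3.36% ± 0.237 (permutation p = 0.00990 in each case). The reverse shares were 35.6% of H3122 R175 and 20.6% of H3122 R273 peaks. Placement mostly moves peaks off promoters, so sets rich in promoter peaks would exceed it between the lines as well. With a reciprocal overlap of at least 0.5, 40% of H2228 R175 and 36.4% of H2228 R273 peaks were shared, and 18.7 and 8.95% in reverse. With the same number of peaks per table the shares were 62.2 and 58.9%, and 56.6 and 51.7% in reverse. The H3122 tables held 2.13 times as many peaks for R175 and 4.07 times as many for R273. Promoter peaks in both H3122 tables and neither H2228 table were listed for 1447 genes, and the reverse for 20. The 1447 came from 11264 genes with a promoter peak in both H3122 tables. They included 10 of 48 such replication genes, among them CDC6, GMNN and GINS2, and 11 of 32 such histone genes. Of 33 such recombination and Fanconi anaemia genes they included 4 (BRCA1, FANCB, FANCE and FANCM), near the share over all genes. These members were named after their values were seen.

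For R175, the promoters highest in H3122 with none in H2228 were TEAD2, a transcription factor of the Hippo pathway, at 17, RND1 at 16.1, TBC1D10A at 14.7, EFEMP2 at 13.3 and PA2G4 at 12.9. In the other direction they were EXOC2 at 10.2, the shared peak of ARMCX5 and ARMCX5-GPRASP2 at 6.80, CHRNB2 at 6.53 and GRM2 at 6.46. For R273, PIM1, a kinase gene, had 14.3, CTNNBIP1 13.9, CASP9, which encodes an initiator caspase, 13.4, DAG1 13.1 and CRIP2 13.1 in H3122 with no promoter peak for R273 in H2228. ALKBH3, a DNA alkylation repair gene, had 8.86, XKR7 8.03, GPC4 7.83, NCAM2 7.52 and AP4E1 7.08 in H2228 with none for R273 in H3122. With promoters of 3 kb, TEAD2, RND1, CASP9, DAG1, CRIP2 and AP4E1 had a peak of the same mutant in both lines, as did TBC1D10A, CASP9, DAG1, CRIP2 and AP4E1 in the tables' own annotation. AP4E1 had none for R273 in either line within 500 bp, nor XKR7 in the tables' own annotation. In all, 9440 of 73596 merged regions had a peak in all 4 tables, 8516 in 3, 17307 in 2 and 38333 in 1.

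**Figure D3:**
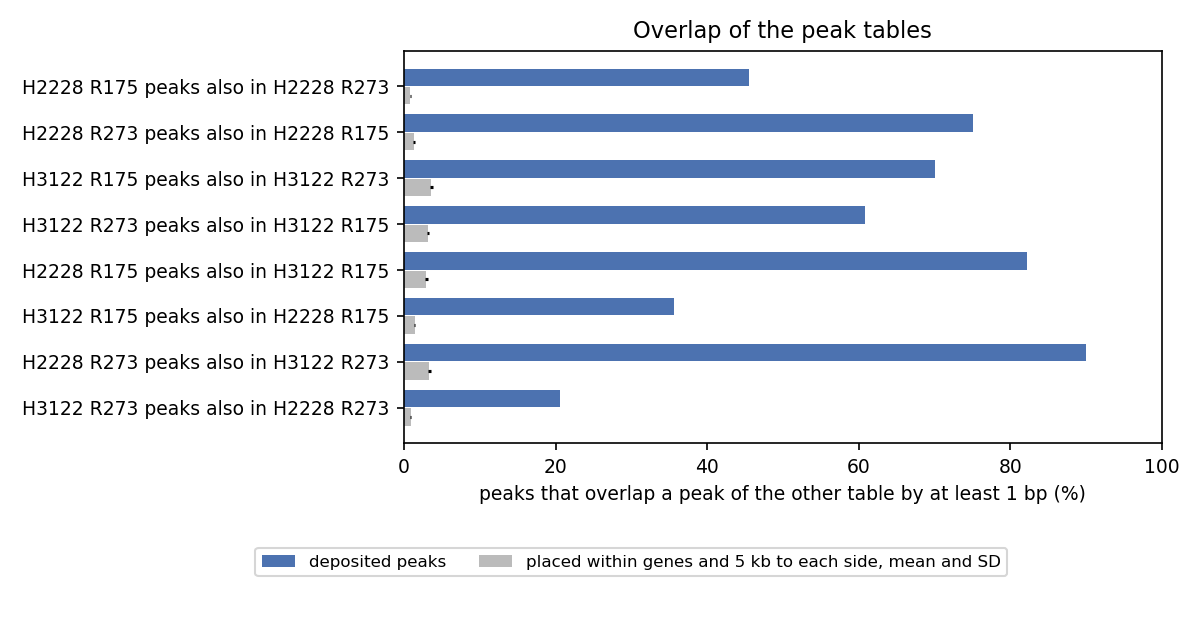
Share of the peaks of 1 table that overlap a peak of another by at least 1 bp (percent, horizontal axis) for each pair (vertical axis), with grey bars for the mean share of 100 random placements within genes and 5 kb to each side and error bars for their SD. The shares run from 20.6 to 90%, and the placed shares stay at or below 3.61%. Placement does not keep peaks at promoters, so any sets rich in promoter peaks would exceed the grey bars.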

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

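This count was made after the data were seen. Peaks on contigs outside chromosomes 1 to 22, X and Y enter no comparison. On the contigs 22_KI270733v1 and Un_GL000220v1, where the tables annotate ribosomal RNA genes, 14 peaks were listed for H2228 R175 and 13 for H2228 R273, and 0 in both H3122 tables. They were picked out as signal in data that no comparison uses. Their fold enrichments ran from 1.63 to 2.37 in H2228 R175 and from 1.59 to 2.38 in H2228 R273. The median implied background at them was 35.3 and 28, against 2.52 and 3.00 over all peaks.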

How the results depend on the processing

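No paired analysis was possible because the tables hold 1 set of peaks per line and mutant, so values per library, with their normalization, filter, replicate block and leaving out of replicates, were not run. Motif shares with all their alternatives and CpG-matched lists need a genome and were not run. Placement within genes, lists matched on q and lists matched on chromosome were chosen after the data were seen. All 24 alternatives set against random placement for the overlap of mutants, 24 for the overlap of lines and 28 for the promoter share stayed above it. For the overlaps this tells little, since placement does not keep peaks at promoters. Overlaps ranged from 27.9 to 75.1% and from 8.95 to 90%, promoter shares from 20 to 64.7%, and odds ratios over genes, which were not set against placement, from 31.7 to 158.

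Values below are in the order H2228 R175, H2228 R273, H3122 R175 and H3122 R273. Peaks numbered 7950, 4096, 26061 and 28383 at a -log10 q of at least 5 and 5712, 3365, 19467 and 17348 at a fold enrichment of at least 5. Counted over the H2228 R273 peaks, 2356 lay in all tables with a reciprocal overlap of at least 0.5 and 4945 with summits within 200 bp. Lists higher than other genes fell to 9 in H2228 R175 at that q, 6 at that fold, and 7, 5, 9 and 9 with the 5000 highest peaks. Lists lower fell to 2 and 2 in H2228 at that q, 1 and 1 at that fold, and 2, 2 and, for H3122 R273, 1 with the 5000 highest. With the background of genes with a promoter peak in at least 1 table, 0, 1, 0 and 0 lists were higher and 0, 0, 0 and 0 lower. That background is made of occupied promoters only, and the cause of the other changes was not tested.

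The occupancy of cell cycle genes in H2228 R175 fell below that of other genes at 21.9% at that q, 18.8% at that fold and 15.6% with the 5000 highest peaks. Against the narrower background, DNA replication (74%), excision and mismatch repair (68.8%) and the cell cycle (71%) in H2228 R175, and excision and mismatch repair (90.6%) and chromatin regulators (91.3%) in H3122 R273, lay below other genes, and the 2 olfactory receptors left lay above in all tables (100%). These comparisons had passed the test among all listed peaks. Another 10 that had not passed also changed side. Among them, in H2228 R273, were DNA replication and recombination, with 23 and 14 occupied promoters, where 7615 of the 12927 background genes were occupied. Neither passed the test as lower. Lists outside the middle 95% of random lists numbered 1 in H2228 with the same number of peaks per table, 3 for promoters of 500 bp and 3 matched on q, where chromatin regulators (1.28) and highly transcribed genes (2.38) joined recombination. At that q and that fold they numbered 2 and 2, none of them those outside among all listed peaks. In H3122 they numbered 1 at that q, 2 at that fold, 1 with equal numbers, 2 and 1 for promoters of 500 bp and 3 kb, and 2 matched on q. The excision and mismatch repair difference in H2228 moved to percentiles 56.4 at that q and 54.6 at that fold. The cause was not tested. The depth of single libraries was not analysed here, so a promoter without a peak was not detected at this depth rather than shown to be free of p53.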

Other observations

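Percentiles of list fold enrichment, the lists matched on q and on chromosome, the test of general promoter occupancy and that of recurrence between lines were chosen after the results were seen. Among occupied promoters of the same table, wild-type p53 target genes had a median fold enrichment at percentiles 93.2, 96.5, 99.88 and 98.7 of random lists in H2228 R175, H2228 R273, H3122 R175 and H3122 R273. Chromatin regulators lay at 99.555, 100, 96.5 and 98.5, and highly transcribed genes at 100, 99.88, 99.945 and 100. Mesenchymal markers lay at 0.450 and 0.530 in the H3122 tables.

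Among recombination and Fanconi anaemia promoters in H2228, 16 of 30 with an R175 peak had none for R273, against a median of 26.7% for lists matched on the q of the R175 peak, where the list had 53.3% (percentile 99.91). With the same number of peaks from both tables the difference lay at percentile 99.925, and against lists with the same chromosomes at 99.96. Among all listed peaks this argues against loss by the q of the R175 peak alone, a longer R175 table or chromosomes short of R273 peaks as the whole cause. The 3 percentiles rescore the same promoters of a list picked for its wide gap in these values. They are therefore not independent support for a difference between the mutants. With a -log10 q of at least 5 the difference was 52.9 points against a random median of 35.3 (percentile 81.4) and with a fold enrichment of at least 5 40 against 33.3 (percentile 68.2), where it had been 53.3 against 20, so the list was not set apart among strong peaks and a part played by weak peaks stays open. That R175 may occupy these promoters more than R273 in H2228 is a hypothesis that a difference between preparations could equally give, since there is 1 table per mutant. In H3122 with equal peak numbers the same list lay at percentile 18.9.

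Occupancy of replication and repair promoters may follow general occupancy of active promoters. Over 153 replication and repair genes, 76.5, 51, 96.1 and 95.4% of promoters were occupied, against 89.2, 76.6, 94.6 and 97.3% of 111 highly transcribed and ribosomal protein genes. Their median fold enrichment lay at percentiles 61.8, 62.4, 76.8 and 97.9 of random lists of occupied promoters. The last lies above the middle 95%. In share, H3122 R175 alone lies above the comparators, at 96.1 against 94.6%, where most promoters of both groups were occupied and the share tells little. Both H2228 tables, with more room, lie below them. General occupancy and an added preference for these genes cannot be told apart.

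A mutant difference that recurs between the lines would give more R175-only promoters in both lines than independent sets. There were 139, against 154 ± 10.6 (SD), and 148 promoters were R175 only in H2228 and R273 only in H3122, against 175.4 ± 11.3. That 148 lies below the range of 154 to 198 for independent sets, which are therefore not a sound chance level. No conclusion is drawn from 139 against 154. Of the 678 R175-only promoters of H3122, 139 were R175 only in H2228, as were 148 of the 771 R273-only promoters of H3122. For R273 only in H2228 the counts were 39 of 678 and 41 of 771. These counts show no leaning to the same mutant in both lines. They neither show nor exclude a difference shared by a small number of promoters, because most promoters of H3122 were occupied with both mutants.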
